A study of Mus musculus with 18 samples.

How the data were processed

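The 18 libraries were made from total RNA of mouse embryonic stem cells, which had been detached with trypsin and lysed in Trizol, with a TruSeq RNA kit. The labels name no culture medium, clone, day or batch, and do not say whether the 3 libraries of a group came from separate cultures. The p-values given here therefore measure the spread between these libraries. The authors deposited TPM (a transcript share scaled to a total of 1000000) for 56551 genes, written to 2 decimals, and each library sums to that total within rounding. TPM keeps no read counts, so the depth of each library is unknown and no counting interval is given. The submitters' processing notes name TopHat2 2.1.1, RSEM, edgeR and the genome build GRCm38.p5. The part each program played, and the annotation release, are not given in the sources used here. A gene whose value is exactly 0 is described as listed at 0, because 86 genes with a median TPM of 5 or more were listed at 0 in at least 1 library, 17 of them protein-coding. The 6 further columns of the deposited table equal the means of the 3 libraries of each group within 0.011 TPM and were not used. Gene symbols and positions came from a GENCODE annotation of GRCm38. It gave a symbol for 55141 genes of the table.

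Values were taken as log2(TPM + 1), which understates the fold change of genes at a few TPM or less. Genes at 1 TPM or more in at least 3 libraries were tested, which left 17842 genes, 945 of them without a symbol and 16897 with a position. A linear model with 1 mean per group was fitted to all 18 libraries with limma 3.58.1 in R 4.3.3 (12 residual degrees of freedom, empirical Bayes with a trend on the mean). Tests were two-sided. Benjamini-Hochberg adjustment was made within each of 10 comparisons, and a gene was called at an adjusted p under 0.05. The number that also changed at least 2-fold is given beside each count. The comparisons were each knockout against WT, Ring1b-KO against Ring1a-KO, the double knockout against Ring1b-KO, Pcgf-6KO against Pcgf-4KO and against the double knockout, and the interaction of the Ring1a and Ring1b knockouts, which asks whether the double knockout differs from the sum of the single knockouts on the log2 scale. Group values are given in TPM as mean ± SD (n = 3), and log2 fold changes as estimate ± SE.

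Gene groups were tested on 25 lists. They held PRC1 subunits not targeted, PRC2 subunits, Hox genes, developmental homeobox genes outside the Hox clusters, core, naive and formative pluripotency genes, endoderm, mesoderm, neuroectoderm and trophoblast genes, germline and meiosis genes, 2-cell-like genes, CDK inhibitors, proliferation genes, p53 targets, imprinted genes, Wnt, Fgf, Bmp and Hedgehog ligands, fibroblast markers, glycolysis and hypoxia, cholesterol synthesis and integrated stress response genes, and the mitochondrially encoded, replication-dependent histone and cytosolic ribosomal protein genes. The test was limma's camera, which compares a list with all other genes, using a preset correlation between genes of 0.01. Tested members at 1 TPM or more in WT were 0 of 37 Hox, 0 of 20 2-cell-like, 9 of 69 other homeobox, 8 of 30 mesoderm, 12 of 25 endoderm and 17 of 35 ligand genes. The rest passed the filter through knockout libraries, so counts of rises against WT in these lists are partly set by the filter, and so are counts between knockouts and for the interaction where the members are high in one of the groups. A list was called at a p under 0.05 adjusted over the 25 lists of its comparison. The test was repeated with the correlation estimated from the data. The preset correlation also called up to 17 lists when the libraries of 2 groups were exchanged, splits which keep part of the group difference. Lists called with both correlations therefore carry more weight than those called with the preset one alone. Neither correlation removes the effect of the filter, because camera compares a list with all other genes, most of them at 1 TPM or more in WT. For lists mostly under 1 TPM in WT, the direction of the list test is therefore partly set by the filter too. The lists share some members: Hand1 and Gata2 are in the mesoderm and the trophoblast lists, Igf2 in the trophoblast and the imprinted lists, Krt19 in the endoderm and the trophoblast lists, and Bmp4 in the naive pluripotency and the ligand lists. For each list the number of called members over all genes tested is followed by the number adjusted over the list alone.

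The comparisons, the lists, the tests and the alternatives were fixed before the data were examined, and so was the rule for the genes named. The rule took the 8 targeted genes, the 6 largest rises and 6 largest falls of each comparison with WT (4 for the other comparisons) among called genes with a mean of 5 TPM or more in the higher group, no overlap between the libraries of the groups and an established symbol, up to 2 rises and 2 falls per list, and Cdkn2a, Cdkn1a, Pou5f1, Nanog, Sox2, Zfp42, Gata4, Gata6, Cdx2 and Hoxd13. Some genes that the rule named are not reported here. Non-overlap of 3 libraries with 3 has a chance of 10%. The alternatives were a pseudocount of 0.1, no filter, a filter of 5 TPM, only the groups compared, median ratio scaling, quantile normalization, a replicate block, an estimated correlation, a minimum change of 2-fold and leaving out each library in turn. After the data had been seen 3 more were added: nuclear protein-coding genes only with TPM rescaled, no genes of chromosomes 6, 11, 16 and Y, and no Ring1a-KO libraries of replicates 2 and 3. List tests under both other scalings were added at that point for Ring1b-KO against Ring1a-KO, the double knockout against Ring1b-KO and the interaction.

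The steps were run on simulated values with known changes, set on the means and spread of the real genes. Between groups, 58.2% to 70.1% of 1.5-fold changes, 74.6% to 89.6% of 2-fold changes and 92.4% to 100% of 4-fold changes were called, and 28.4%, 68.7% and 84.8% for the interaction. No simulated change was called with the wrong sign, and 5 to 15 unchanged genes were called in each comparison. A list shifted by 0.5 (log2) was found in each of the 10 comparisons, and none of the other 24 lists was called. The simulated noise was independent for each gene, so this does not test false list calls from correlated genes. Fewer genes were changed in the simulations than were called in the real comparisons, so the recovery rates may differ there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.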

Results

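Polycomb repressive complex 1 (PRC1) is a chromatin complex that ubiquitylates a core histone and keeps developmental genes silent in embryonic stem cells. Its catalytic subunit is either Ring1a (gene Ring1) or Ring1b (gene Rnf2), and each complex holds 1 of 6 Pcgf proteins (Pcgf4 is the product of Bmi1). RNA was measured in WT cells and in cells labelled as knockouts of Ring1a, of Ring1b, of both (Ring1a/b-dKO), of Pcgf1, Pcgf3, Pcgf5 and Pcgf6 (Pcgf-4KO) and of all 6 Pcgf genes (Pcgf-6KO), with 3 libraries in each of 6 groups. Values are in TPM, which hides the depth of each library. Group values below are means ± SD of 3 libraries, and adjusted p-values are from limma. The number of genes at 1 TPM or more was 14213 ± 10.1 in WT, 14334 ± 101 in Ring1a-KO, 15616 ± 76.6 in Ring1b-KO, 15821 ± 14 in the double knockout, 15319 ± 42.8 in Pcgf-4KO and 16384 ± 180 in Pcgf-6KO. Libraries of a group lay 0.407 to 0.487 apart (root mean square log2 distance, mean over pairs). By the median SD of log2 values over genes, Pcgf-6KO libraries varied most, at 0.151 against 0.083 to 0.114 in the other groups, and its replicates 1 and 3 differed by a median of 0.232. From WT, the mean distance was 0.547 for Ring1a-KO, 0.799 for Ring1b-KO, 0.942 for the double knockout, 0.951 for Pcgf-4KO and 1.2 for Pcgf-6KO. The double knockout lay 0.597 from Pcgf-4KO, less than either lay from WT.

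The targeted genes differed in how far their transcripts fell. Pcgf6 (ENSMUSG00000025050, GRCm38 chromosome 19, 47033617 to 47050906) was at 53.01 ± 0.26 TPM in WT, 0.06 ± 0.05 in Pcgf-4KO and 10.6 ± 0.78 in Pcgf-6KO. Pcgf1 (ENSMUSG00000069678, chromosome 6, 83077869 to 83080855) was at 10.9 ± 0.99 TPM in WT, 1.23 ± 1.2 in Pcgf-4KO and 3.03 ± 1.11 in Pcgf-6KO. Pcgf2 (ENSMUSG00000018537, chromosome 11, 97688823 to 97700497), left intact in Pcgf-4KO, fell from 68.6 ± 4.71 to 16.8 ± 1.28 TPM in Pcgf-6KO, and by less to 55.3 ± 2.13 TPM in Pcgf-4KO. Rnf2 (ENSMUSG00000026484, chromosome 1, 151458004 to 151500955) fell from 71.3 ± 5.24 TPM in WT to 49.4 ± 3.13 in Ring1b-KO (log2 fold change -0.52 ± 0.08, adjusted p = 6.32e-05) and 22.8 ± 2.94 in the double knockout (-1.61 ± 0.08, adjusted p = 1.29e-10). Ring1 (ENSMUSG00000024325, chromosome 17, 34020792 to 34024680) was at 7.21 ± 0.18 TPM in WT. It was not called in Ring1a-KO, at 4.05 ± 1.31 TPM (adjusted p = 0.0705), but was called without Ring1a-KO replicate 1, at a log2 fold change of -0.93. In the double knockout Ring1 was at 6.09 ± 3.33 TPM and not called (adjusted p = 0.311), with single libraries at 2.74, 6.12 and 9.4 TPM, and was called without replicate 3, at -0.67, and with quantile normalization, at -0.83. Pcgf3 (ENSMUSG00000033623, chromosome 5, 108461232 to 108506976) was not called in Pcgf-4KO or Pcgf-6KO, at 11.8 ± 0.5 and 12.4 ± 2.5 TPM against 13.2 ± 0.43 TPM in WT. Under median ratio scaling and quantile normalization Pcgf3 was called lower in both, at -0.35 and -0.46 in Pcgf-4KO and -0.26 and -0.48 in Pcgf-6KO. Pcgf5 (ENSMUSG00000024805, chromosome 19, 36348309 to 36460970) rose from 9.55 ± 0.56 TPM to 14.5 ± 1.24 and 22.1 ± 1.11 in these groups. Bmi1 (ENSMUSG00000026739, chromosome 2, 18677018 to 18686629) rose from 1.6 ± 0.82 TPM to 15.6 ± 1.09 in Pcgf-6KO. In all, 7 of the 14 pairs of a targeted gene and a knockout of it were called lower. A gene-level TPM does not show whether an exon was deleted.

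**Figure D1:**
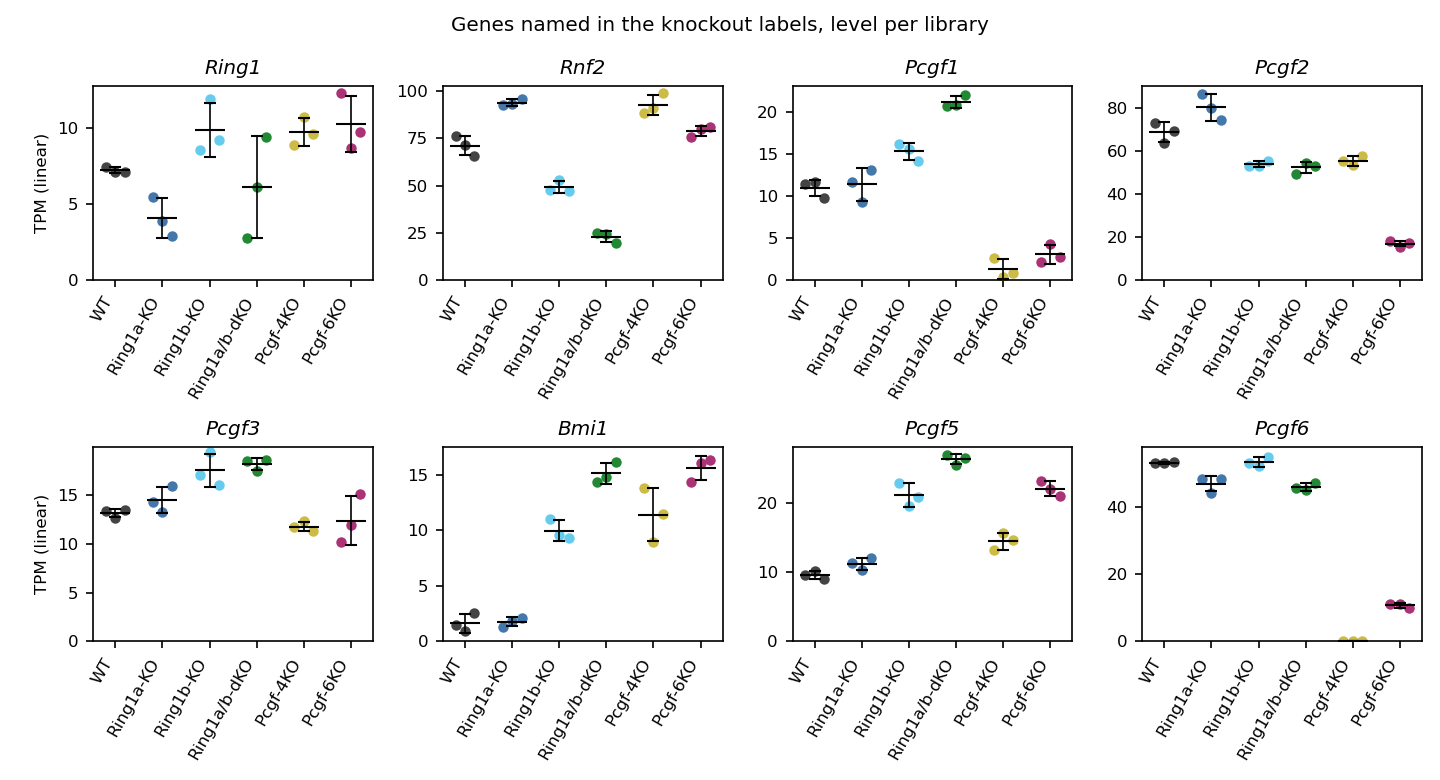
TPM of the 8 targeted genes on linear axes, with a dot per library, a black bar at the mean and an error bar of 1 SD for each of the 6 groups (n = 3). Pcgf6 is at 0.06 TPM in Pcgf-4KO, and Rnf2 is lowest in the double knockout, at 22.8 TPM.

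**Figure D2:**
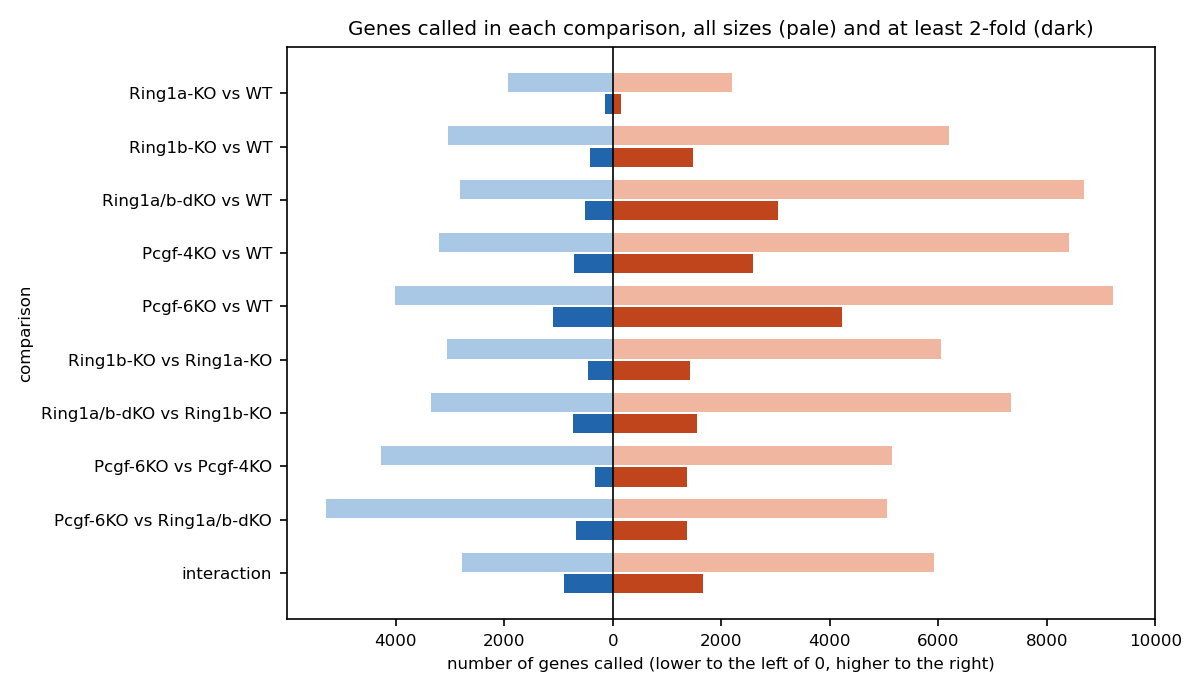
Number of genes called lower (left) and higher (right) in each of the 10 comparisons, with all called genes as pale bars and those changed at least 2-fold as dark bars. Pcgf-6KO against WT has 9216 genes called higher and 4020 lower, a split of 69.6% higher that becomes 46.6% with quantile normalization.

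**Figure D3:**
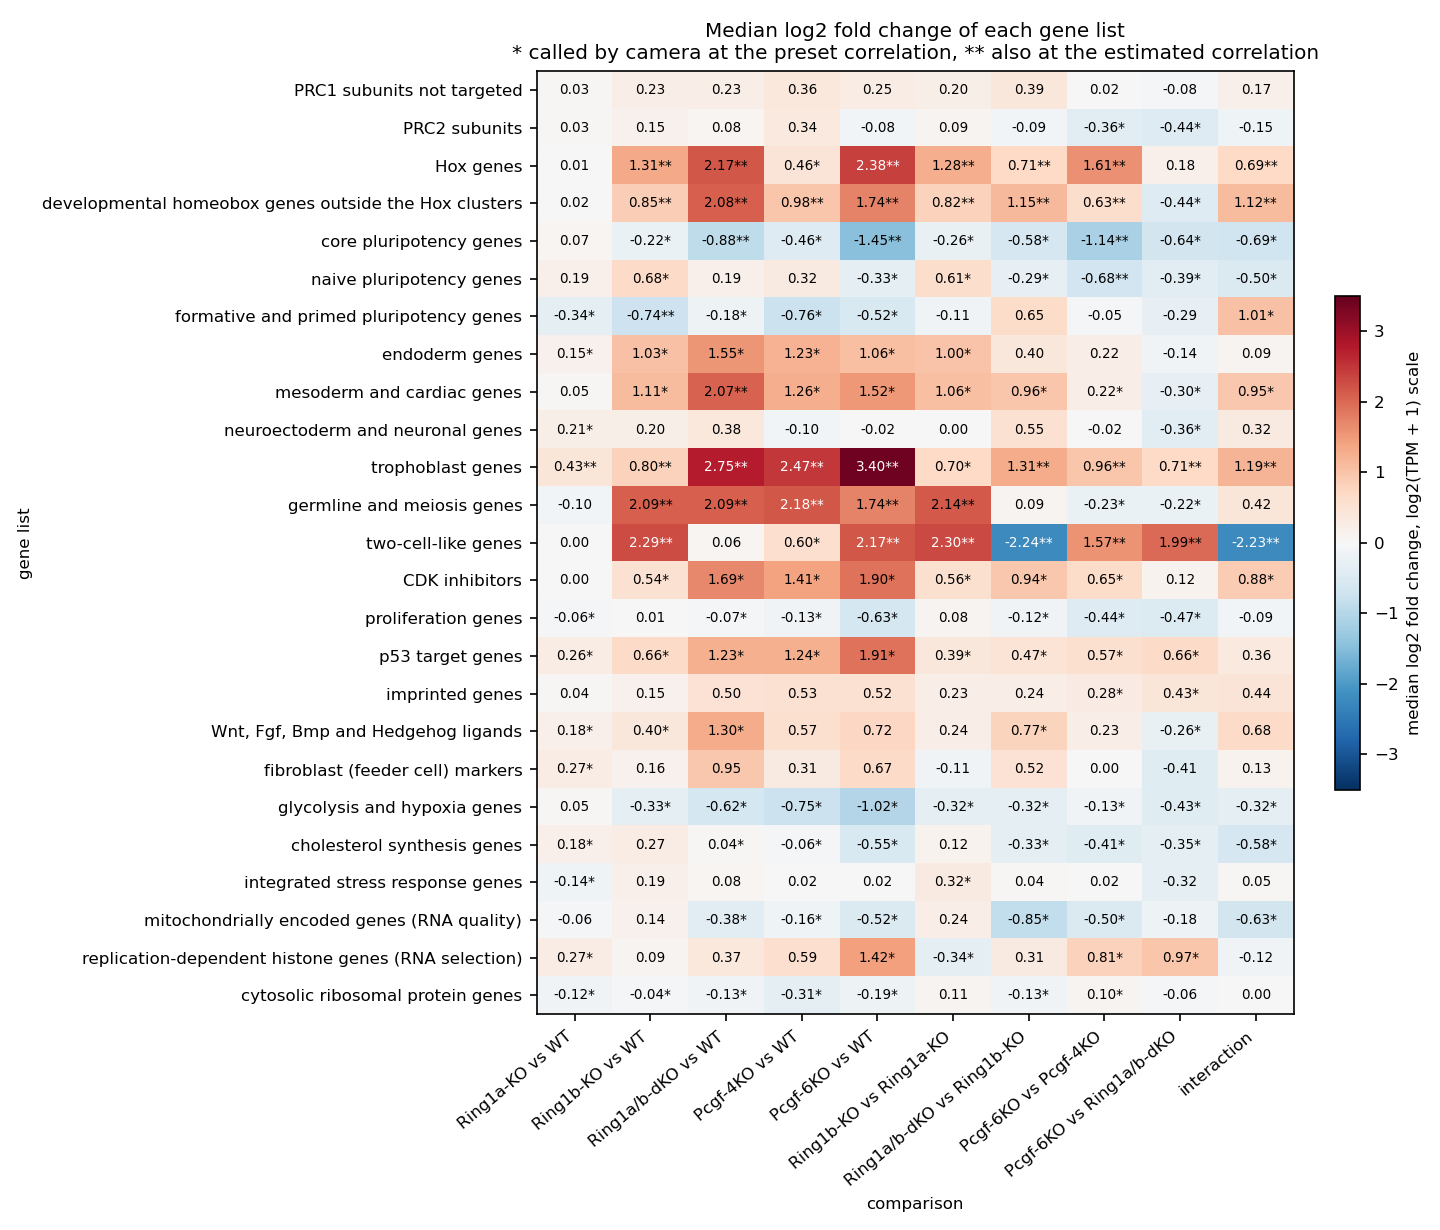
Median log2 fold change of 25 gene lists (vertical) in 10 comparisons (horizontal), with 1 asterisk for lists called with the preset correlation and a pair for those also called with an estimated correlation. The Hox genes lie at 1.31 in Ring1b-KO, 2.17 in the double knockout and 2.38 in Pcgf-6KO against WT.

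Ring1a-KO, labelled as lacking Ring1a, was compared with WT, although Ring1 itself was not called. Trophoblast genes, which mark the lineage of the placenta, were mostly higher. Hand1 rose from 2.45 ± 0.24 to 4.29 ± 0.28 TPM and Igf2 from 19.04 ± 0.87 to 31.3 ± 1.65 TPM. Of the formative pluripotency genes, switched on as cells leave the naive state, 9 of 18 were lower, a list not called with an estimated correlation (adjusted p = 0.121). Lef1, a Wnt effector, fell from 5.97 ± 0.38 to 0.39 ± 0.04 TPM and Pou3f1 from 16.7 ± 1.26 to 4.32 ± 0.24 TPM. Mest (ENSMUSG00000051855, chromosome 6, 30723547 to 30748465), an imprinted gene, fell from 76.0 ± 1.62 to 1.41 ± 0.14 TPM. Mid1 (ENSMUSG00000035299, chromosome X, 169685199 to 170005736) fell from 62.5 ± 1.02 to 1.49 ± 0.08 TPM (log2 fold change -4.67 ± 0.11, adjusted p = 3.79e-13) and the kinase gene Pim2 from 97.8 ± 2.6 to 11.1 ± 1.35 TPM. The fall of Mid1, here and in the double knockout and Pcgf-4KO, cannot be told apart from that of Y-linked transcripts, given below. Pla2g7 rose from 4.7 ± 0.53 to 21.8 ± 2.13 TPM and the membrane protein gene Emp1 from 5.57 ± 0.44 to 23.9 ± 1.03 TPM. Among imprinted genes Phlda2, a brake on placental growth, rose from 169 ± 0.64 to 339 ± 12.2 TPM. The Nodal antagonist gene Lefty2 rose from 136 ± 5.61 to 353 ± 8.3 TPM and the basement membrane gene Col4a1 from 8.06 ± 0.45 to 25.8 ± 1.04 TPM. The pluripotency factor gene Klf4 fell from 16.04 ± 0.66 to 3.34 ± 0.23 TPM, and Dnmt3b, a DNA methyltransferase gene, from 310.3 ± 7.21 to 157 ± 6.83 TPM. Pou5f1 (1050.2 ± 43.3 against 1112 ± 9.62 TPM) and Sox2 (258 ± 25.2 against 247 ± 6.43 TPM) were not called. Of 21 trophoblast genes tested 13 rose, 1 fell and 7 were not called (13 and 1 adjusted over the list alone), with a median log2 change of 0.43. The trophoblast list was called with the preset correlation (adjusted p = 2.02e-06) and with an estimated correlation (adjusted p = 0.0155). Of 18 formative genes 9 fell, 1 rose and 8 were not called (9 and 2 adjusted over the list alone), with a median of -0.35 and an adjusted p of 2.02e-06 with the preset correlation. Limma called none of the 37 Hox genes, of which 1 passed an unadjusted p of 0.05, and none of the 20 2-cell-like genes, of which 0 passed it. In all 4123 genes were called, 2193 higher and 1930 lower, against 6195 at an unadjusted p under 0.05. The share called higher was 53.2%, 54.8% under median ratio scaling, 48.5% with quantile normalization and 60.1% with nuclear protein-coding genes only, so the larger side depends on the scaling. At least 2-fold changes were seen in 302 genes, 151 in each direction. The small RNA share of TPM was 2.883% and 1.318% in Ring1a-KO replicates 2 and 3, against 0.21% in replicate 1 and 0.327% to 0.666% in the other groups. The small nuclear RNA gene Rn7sk rose from 14.8 ± 2.11 to 273 ± 325 TPM (adjusted p = 0.0209), a call lost without WT replicate 2 or 3 and without Ring1a-KO replicate 2 or 3. Without Ring1a-KO replicates 2 and 3 together, 2169 genes were called, 1412 higher and 757 lower (65.1% higher), from a single Ring1a-KO library assumed to vary like the other groups.

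More genes were called in Ring1b-KO, labelled as lacking Ring1b, where Rnf2 transcripts were lowered but remained at 49.4 TPM. Germline genes rose. Dazl (ENSMUSG00000010592, chromosome 17, 50279395 to 50293636), an RNA-binding protein gene of germ cells, rose from 1.09 ± 0.17 to 87.0 ± 2.02 TPM (log2 fold change 5.40 ± 0.08, adjusted p = 3.23e-16). Mael, which silences transposons, rose from 4.65 ± 0.27 to 141 ± 3.86 TPM, and Fkbp6 from 0.27 ± 0.15 to 46.1 ± 2.65 TPM. The imprinted transcript H19 (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143) rose from 0.29 ± 0.16 to 68.4 ± 3 TPM. Genes of 2-cell-like cells, a rare state with transcripts of the early embryo, rose too. Zscan4f (ENSMUSG00000070828, chromosome 7, 11397915 to 11402318) was listed at 0 in WT and was at 19.8 ± 0.83 TPM in Ring1b-KO, and Zscan4c, also listed at 0, was at 11.8 ± 0.72 TPM. Hoxd13 (ENSMUSG00000001819, chromosome 2, 74668310 to 74671599), which patterns limbs, rose from 0.47 ± 0.14 to 9.46 ± 0.84 TPM and Hoxa7 from 0.21 ± 0.06 to 9.22 ± 0.67 TPM. The endoderm factor gene Gata4 rose from 0.51 ± 0.04 to 9.47 ± 0.51 TPM and Gata6 from 0.1 ± 0.04 to 5.54 ± 0.24 TPM. Nanog (ENSMUSG00000012396, chromosome 6, 122707489 to 122714633), a core pluripotency factor gene, rose from 108 ± 3.5 to 387 ± 10.6 TPM (1.83 ± 0.05, adjusted p = 2.24e-13) and Tbx3, of the naive list, from 3.58 ± 1.58 to 61.3 ± 0.69 TPM. Among falls were Ifitm1, from 760.5 ± 42.9 to 101 ± 3.51 TPM, Glyatl3, from 23.5 ± 1.93 to 1.02 ± 0.4 TPM, and the formative gene Foxp1, from 52.3 ± 0.77 to 7.32 ± 0.78 TPM. The neuronal tubulin gene Tubb3 fell from 121 ± 3.54 to 28.5 ± 0.64 TPM. The PRC1 subunit gene Cbx8 rose from 0.25 ± 0.08 to 6.65 ± 0.88 TPM and Phc1 fell from 287 ± 5.29 to 114 ± 2.19 TPM. The cell cycle inhibitor gene Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653) rose from 14.5 ± 0.41 to 50.5 ± 3.18 TPM.

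By list, 46 of 49 germline genes rose in Ring1b-KO, 1 fell and 2 were not called (46 and 2 adjusted over the list alone), with a median log2 change of 2.09. Of the 37 Hox genes 35 rose and 2 were not called (35 adjusted over the list alone), with a median of 1.31, and of 69 other homeobox genes 58 rose, 1 fell and 10 were not called (58 and 1 adjusted over the list alone), with a median of 0.85. Each of the 20 2-cell-like genes tested rose (20 adjusted over the list alone), with a median of 2.29. At 1 TPM or more in WT were 0 of the 20 2-cell-like and 0 of the 37 Hox genes, so they were tested only because knockout libraries reached 1 TPM, and these counts of rises are in large part set by the filter. All 3622 tested genes under 1 TPM in WT had a median of 0.463 in Ring1b-KO, and 0 of them fell at least 2-fold. Trophoblast genes went higher in 17 of 21 cases, with 2 lower and 2 not called (17 and 2 adjusted over the list alone), and 13 of 18 formative genes fell, with 1 higher and 4 not called (14 and 1 adjusted over the list alone). These 6 lists were called with both correlations. The adjusted p with an estimated correlation was 7.93e-04 for the germline list, 4.37e-04 for Hox genes, 9.09e-04 for the other homeobox genes, 3.98e-04 for 2-cell-like genes, 0.0108 for trophoblast genes and 0.0378 for formative genes. Endoderm genes, of which 20 of 25 rose, 2 fell and 3 were not called (20 and 2 adjusted over the list alone), and mesoderm genes, of which 25 of 30 rose, 1 fell and 4 were not called (25 and 1 adjusted over the list alone), were called with the preset correlation, with medians of 1.03 and 1.11 and an adjusted p of 0.0602 and 0.0584 with an estimated correlation. In all 9247 genes were called, 6200 higher and 3047 lower, and 1894 changed at least 2-fold, 1472 higher and 422 lower. The median log2 change of all genes was 0.13, and the list tests are relative to all other genes. The share called higher was 67% here, 62.2% under median ratio scaling and 46.4% with quantile normalization.

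In the double knockout, labelled as lacking both catalytic subunits of PRC1, genes of the trophoblast, mesoderm and homeobox lists rose and core pluripotency genes fell. Hand1 (ENSMUSG00000037335, chromosome 11, 57828705 to 57832818), a factor of trophoblast giant cells and heart, rose from 2.45 ± 0.24 to 154 ± 6.66 TPM (log2 fold change 5.49 ± 0.06, adjusted p = 4.68e-18). Igf2 (ENSMUSG00000048583, chromosome 7, 142650766 to 142666816), an imprinted growth factor gene, rose from 19.04 ± 0.87 to 543 ± 6.45 TPM (4.76 ± 0.04, adjusted p = 6.73e-19). The germline gene Taf7l (ENSMUSG00000009596, chromosome X, 134460118 to 134476490) rose from 1 ± 0.05 to 99.6 ± 3.26 TPM and Tex101 from 0.66 ± 0.46 to 70.7 ± 4.03 TPM. The placental homeobox gene Esx1 rose from 1.38 ± 0.54 to 68.5 ± 3.41 TPM and the gluconeogenic gene Fbp2 from 0.84 ± 0.06 to 47.3 ± 0.79 TPM. Hoxd13 rose to 17.8 ± 0.75 TPM, Hoxa10 from 0.05 ± 0.09 to 11.9 ± 0.64 TPM, Barx1 from 0.84 ± 0.21 to 29.9 ± 2.33 TPM and Pitx1 from 0.04 ± 0.04 to 14.4 ± 1.04 TPM. The heart factor gene Nkx2-5 rose from 0.26 ± 0.15 to 15.6 ± 0.49 TPM, and Cdx2, a trophoblast and gut factor gene, from 0.15 ± 0.09 to 8.83 ± 0.15 TPM. Gata4 and Gata6 reached 15.2 ± 0.71 and 9.86 ± 0.82 TPM. Nanog fell from 108 ± 3.5 to 36.3 ± 1.86 TPM (-1.55 ± 0.05, adjusted p = 7.01e-13), Pou5f1 from 1112 ± 9.62 to 592 ± 17.3 TPM, Sox2 from 247 ± 6.43 to 136 ± 1.46 TPM, and the Nodal co-receptor gene Tdgf1 (ENSMUSG00000032494, chromosome 9, 110939603 to 110946158) from 693 ± 3.66 to 154 ± 3.09 TPM. Among the core pluripotency genes Dppa2 rose from 83.5 ± 2.36 to 203 ± 5.03 TPM. Zfp42, which is not in that list, rose from 56.7 ± 2.32 to 77.1 ± 2.01 TPM. Mest fell to 2.07 ± 0.19 TPM, Mid1 to 1.5 ± 0.22 TPM, and the hormone precursor gene Trh (ENSMUSG00000005892, chromosome 6, 92242061 to 92244650) from 196 ± 0.6 to 9.63 ± 0.4 TPM. The PRC1 subunit gene Cbx8 rose from 0.25 ± 0.08 to 14.5 ± 1.36 TPM, and Phc1 fell to 70.9 ± 0.59 TPM. Cdkn1a rose from 26.3 ± 0.53 to 102 ± 2.71 TPM, Cdkn2a to 67.0 ± 5.17 TPM, and the p53 targets Perp from 14.1 ± 1.51 to 102 ± 2.38 TPM and Btg2 from 11.6 ± 0.73 to 63.7 ± 1.39 TPM.

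All 37 tested Hox genes, none of them at 1 TPM in WT and so nearly unable to fall, rose in the double knockout (37 adjusted over the list alone), with a median log2 change of 2.17, and 68 of 69 other homeobox genes rose with 1 not called (68 adjusted over the list alone), with a median of 2.08. All 3622 tested genes under 1 TPM in WT had a median of 0.592 in the double knockout, and 0 of them fell at least 2-fold. Trophoblast genes rose in 20 of 21 cases with 1 not called (20 adjusted over the list alone), with a median of 2.75. In the germline list 44 of 49 genes rose, 1 fell and 4 were not called (44 and 1 adjusted over the list alone). Of 30 mesoderm genes 28 rose, 1 fell and 1 was not called (28 and 1 adjusted over the list alone), with a median of 2.07. Core pluripotency genes fell in 14 of 18 cases, with 3 higher and 1 not called (14 and 3 adjusted over the list alone) and a median of -0.88. These 6 lists were called with both correlations, and the adjusted p with an estimated correlation was 5.67e-04 for Hox genes, 3.85e-04 for the other homeobox genes, 0.00114 for trophoblast genes, 0.00704 for germline genes and 0.0476 for both the mesoderm and the core pluripotency genes. The 2-cell-like genes, all higher in Ring1b-KO, were called in 2 of 20 cases here (2 adjusted over the list alone), with a median of 0.06, a mean of 0.13 and a test against all other genes in the lower direction that was not called (adjusted p = 0.499). Of 8 CDK inhibitor genes 7 rose and 1 was not called (7 adjusted over the list alone), and of 23 p53 targets 19 rose and 4 were not called (20 adjusted over the list alone). These were called with the preset correlation, with medians of 1.69 and 1.23, and had an adjusted p of 0.072 and 0.204 with an estimated correlation. In all 11489 genes were called, 8677 higher and 2812 lower, and 3544 changed at least 2-fold, 3036 higher and 508 lower. Mitochondrially encoded genes held 5.25% ± 0.219 of TPM against 6.63% ± 0.25 in WT, and replication-dependent histone genes 0.0383% ± 0.00153 against 0.0227% ± 0.000577. Among these mt-Nd2 fell from 2099.9 ± 49.95 to 1225 ± 64.5 TPM, Hist1h2bc rose from 8.58 ± 1.15 to 61.6 ± 3.38 TPM and Hist1h1c from 5.66 ± 0.97 to 38.2 ± 1.38 TPM. The median log2 change of all genes was 0.28, which became 0.13 under median ratio scaling and -0.03 with quantile normalization. The share called higher was 75.5%, 62.2% and 48.2% in the same order.

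In Pcgf-4KO, which by its labels lacks Pcgf1, Pcgf3, Pcgf5 and Pcgf6 and keeps Pcgf2 and Bmi1, germline and trophoblast genes rose. H19 rose from 0.29 ± 0.16 to 246 ± 5.42 TPM (log2 fold change 7.59 ± 0.10, adjusted p = 3.44e-17). The germline genes Rhox13 and Tex101 rose from 0.42 ± 0.15 to 129 ± 2.79 TPM and from 0.66 ± 0.46 to 120 ± 4.93 TPM, and the X-linked Mageb4 from 0.28 ± 0.02 to 72.3 ± 0.46 TPM. Hand1 rose to 169 ± 5.15 TPM (5.63 ± 0.06, adjusted p = 1.31e-18) and Igf2 to 439 ± 4.97 TPM. The Wnt ligand gene Wnt7b rose from 1.79 ± 0.14 to 35.8 ± 1.63 TPM. Hoxd13 rose to 2.03 ± 0.18 TPM, while Barx1 reached 22.9 ± 2.2 TPM. Zscan4f, listed at 0 in WT, was at 2.08 ± 0.35 TPM. The imprinted transcripts Meg3 (ENSMUSG00000021268, chromosome 12, 109541001 to 109571726) and Rian fell from 166 ± 6.08 to 2.99 ± 0.81 TPM and from 218 ± 7.89 to 4.93 ± 0.47 TPM. Trh fell to 3.75 ± 0.77 TPM and Mid1 to 1.32 ± 0.12 TPM. The formative factor gene Otx2 fell from 13.8 ± 0.67 to 0.29 ± 0.18 TPM (-3.53 ± 0.10, adjusted p = 1.23e-13), and Lefty1 from 194 ± 7.75 to 10.2 ± 0.96 TPM. Pou5f1 fell to 621 ± 5.44 TPM, Sox2 to 172 ± 4.22 TPM and Tdgf1 to 156 ± 1.98 TPM, whereas Zfp42 rose to 105 ± 1.91 TPM and Dnmt3l from 339 ± 6.16 to 973 ± 26 TPM. Nanog, at 117 ± 2.1 TPM, had a log2 fold change of 0.12 (adjusted p = 0.0385) that became -0.10 under median ratio scaling and -0.01 with quantile normalization. Cdkn1a rose to 111 ± 1.12 TPM and the p53 targets Perp to 109 ± 0.18 TPM and Plk2 from 13.2 ± 0.53 to 91.5 ± 1.09 TPM.

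Of 21 trophoblast genes 20 rose in Pcgf-4KO and 1 was not called (20 adjusted over the list alone), with a median log2 change of 2.47. In the germline list 45 of 49 rose, 2 fell and 2 were not called (45 and 2 adjusted over the list alone), with a median of 2.18, and of 69 homeobox genes outside the Hox clusters 59 rose, 1 fell and 9 were not called (62 and 1 adjusted over the list alone), with a median of 0.98. With an estimated correlation the adjusted p was 0.00268 for trophoblast genes, 0.0105 for germline genes and 0.0104 for the homeobox genes, and no other list was called by camera. Hox genes rose in 25 of 37 cases with 12 not called (25 adjusted over the list alone), with a median of 0.46 and an adjusted p of 0.00312, which was 0.0832 with an estimated correlation. All 3622 tested genes under 1 TPM in WT, the level of these Hox genes, had a median of 0.516. The Hox median was therefore not above that of genes at this level. No test compared these lists with each other, and the log2(TPM + 1) scale shrinks the medians of genes near 0, with 0 of 37 Hox, 34 of 49 germline and 14 of 21 trophoblast genes at 1 TPM or more in WT. The 2-cell-like genes rose in 16 of 20 cases with 4 not called (17 adjusted over the list alone), with a median of 0.60 and an adjusted p of 0.00363, which was also 0.0832 with an estimated correlation. Their median of 0.60 lay little above the 0.516 of all genes under 1 TPM in WT. Core pluripotency genes fell in 12 of 18 cases, with 5 higher and 1 not called (12 and 5 adjusted over the list alone), and their adjusted p was 0.161 with an estimated correlation. Of 58 cytosolic ribosomal protein genes 46 fell and 12 were not called (46 adjusted over the list alone), with a median of -0.31, an adjusted p of 1.20e-14 and of 0.239 with an estimated correlation, and quantile normalization reduced the median to -0.09 and ended the call. In all 11602 genes were called, 8406 higher and 3196 lower, and 3293 changed at least 2-fold, 2584 higher and 709 lower. The share of replication-dependent histone genes in TPM was 0.0503% ± 0.00208 against 0.0227% ± 0.000577 in WT, with Hist1h1c at 74.2 ± 0.56 against 5.66 ± 0.97 TPM and Hist1h2bc at 102 ± 3.49 against 8.58 ± 1.15 TPM. The median log2 change of all genes was 0.25, 0.08 under median ratio scaling and -0.02 with quantile normalization, and the share called higher was 72.5%, 57.6% and 49.6%.

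Pcgf-6KO, which lacks all 6 Pcgf proteins by its labels, had the most called genes of the 10 comparisons. The keratin gene Krt18 (ENSMUSG00000023043, chromosome 15, 102028180 to 102032027) rose from 35.9 ± 3.61 to 2863 ± 52 TPM (log2 fold change 6.28 ± 0.06, adjusted p = 3.25e-19), the chaperone gene Cryab (ENSMUSG00000032060, chromosome 9, 50751325 to 50756636) from 3.22 ± 0.24 to 822 ± 16.3 TPM, Hand1 to 525 ± 16.5 TPM (7.25 ± 0.06, adjusted p = 6.02e-20) and the epidermal gene Sbsn from 3.32 ± 0.2 to 279 ± 5.43 TPM. H19 rose to 486 ± 23.3 TPM and Igf2 to 734 ± 19.4 TPM. The basement membrane genes Col4a1 and Col4a2 rose to 140.4 ± 31 and 88.0 ± 14.8 TPM, from 8.06 ± 0.45 and 2.8 ± 0.08 TPM. Hoxb9 rose from 0.06 ± 0.05 to 16.3 ± 0.2 TPM, Hoxa7 to 15.97 ± 1 TPM, Hoxd13 to 11.7 ± 0.73 TPM and Msx2 from 0.53 ± 0.12 to 17.2 ± 0.38 TPM. Zscan4f was at 13.96 ± 1.83 TPM, against a value listed at 0 in WT. Core pluripotency genes changed in both directions. Sox2 fell from 247 ± 6.43 to 46.8 ± 1.39 TPM (-2.38 ± 0.06, adjusted p = 1.14e-14), Pou5f1 from 1112 ± 9.62 to 412 ± 22.3 TPM, Nanog from 108 ± 3.5 to 24.5 ± 0.95 TPM, Tdgf1 to 32.5 ± 1.39 TPM and Fgf4 from 110 ± 4.77 to 11.9 ± 1.16 TPM. Dnmt3l rose from 339 ± 6.16 to 618 ± 22.3 TPM and Dppa2 from 83.5 ± 2.36 to 152 ± 6.61 TPM, as did Tbx3 of the naive list, to 17.9 ± 2.84 TPM, and Cldn6 of the formative list, from 52.8 ± 2.72 to 183 ± 4.77 TPM. Zfp42 was called higher, at 65.7 ± 3.15 against 56.7 ± 2.32 TPM (log2 fold change 0.21), but its value was 0.04 under median ratio scaling and -0.04 with quantile normalization, neither called higher. Trh fell to 0.94 ± 0.13 TPM (-6.66 ± 0.09, adjusted p = 1.53e-17), Lefty1 to 5.21 ± 1.24 TPM, Lefty2 to 5.61 ± 1.33 TPM, Ifitm1 to 25.8 ± 3.09 TPM, and the oncogene Mycn from 211 ± 1.78 to 9 ± 0.2 TPM. The cell cycle inhibitor gene Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727) rose from 26.3 ± 0.53 to 261 ± 12.1 TPM (3.26 ± 0.04, adjusted p = 7.29e-18), Cdkn2a to 91.3 ± 7.71 TPM, and the apoptosis gene Perp (ENSMUSG00000019851, chromosome 10, 18845020 to 18857073) to 314 ± 3.93 TPM. The replication genes Mcm3 and Pcna fell from 291 ± 9.3 to 119 ± 1.68 TPM and from 311 ± 6.27 to 131 ± 7.51 TPM.

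All 37 tested Hox genes rose in Pcgf-6KO (37 adjusted over the list alone), with a median log2 change of 2.38, and so did all 20 tested 2-cell-like genes (20 adjusted over the list alone), with a median of 2.17. As 0 of 37 and 0 of 20 were at 1 TPM or more in WT, they passed the filter only through knockout libraries, and these counts depend on that choice. All 3622 tested genes under 1 TPM in WT had a median of 0.912 in Pcgf-6KO, and 0 of them fell at least 2-fold. Of 69 other homeobox genes 63 rose and 6 were not called (63 adjusted over the list alone), with a median of 1.74, and of 21 trophoblast genes 20 rose and 1 was not called (20 adjusted over the list alone), with a median of 3.40. Germline genes rose in 43 of 49 cases, with 4 lower and 2 not called (43 and 4 adjusted over the list alone) and a median of 1.74, and core pluripotency genes fell in 15 of 18 cases, with 2 higher and 1 not called (15 and 2 adjusted over the list alone) and a median of -1.45. These 6 lists were called with both correlations. The adjusted p with an estimated correlation was 0.00188 for the Hox, other homeobox and trophoblast genes, 0.00253 for 2-cell-like genes, and 0.0323 for the germline and the core pluripotency genes. Of 30 proliferation genes 25 fell, 2 rose and 3 were not called (25 and 2 adjusted over the list alone), and 22 of 23 p53 targets rose with 1 not called (22 adjusted over the list alone). Their medians were -0.63 and 1.91, and the adjusted p of 9.18e-11 and 4.06e-07 became 0.0638 and 0.115 with an estimated correlation. Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, rose in 45 of 55 cases with 10 not called (45 adjusted over the list alone). Their median was 1.42 with an adjusted p of 0.00315, and 0.432 with an estimated correlation. Their share of TPM was 0.101% ± 0.002 in Pcgf-6KO against 0.0227% ± 0.000577 in WT, and the share of mitochondrially encoded genes was 4.02% ± 0.561 against 6.63% ± 0.25. In all 13236 genes were called, 9216 higher and 4020 lower, and 5327 changed at least 2-fold, 4222 higher and 1105 lower. Of the genes under 1 TPM in WT 1634 of 3622 rose at least 2-fold, and of the genes at 20 TPM or more in WT 448 rose and 531 fell at least 2-fold. The median log2 change of all genes was 0.33, 0.19 under median ratio scaling and -0.06 with quantile normalization, and the share called higher was 69.6%, 61.3% and 46.6%.

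Ring1b-KO compared with Ring1a-KO tests directly whether the single knockouts differ. Germline, Hox and 2-cell-like genes were higher in Ring1b-KO. Dazl was at 87.0 ± 2.02 TPM in Ring1b-KO and 1 ± 0.03 TPM in Ring1a-KO (log2 fold change 5.46 ± 0.08, adjusted p = 2.75e-16), and Taf7l at 29.6 ± 1.48 and 0.78 ± 0.26 TPM. The pluripotency genes Klf4 (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466) and Tbx3 were also higher in Ring1b-KO, Klf4 at 61.3 ± 0.41 against 3.34 ± 0.23 TPM (3.85 ± 0.08, adjusted p = 1.18e-14) and Tbx3 at 61.3 ± 0.69 against 1.73 ± 0.82 TPM. Mest was at 46.4 ± 0.6 and 1.41 ± 0.14 TPM. Higher in Ring1a-KO were Gap43, a growth cone gene, at 45.0 ± 1.13 against 3.25 ± 0.56 TPM, the keratin gene Krt17 at 135 ± 6.93 against 15.6 ± 0.82 TPM, Prx at 71.4 ± 3.01 against 7.27 ± 0.29 TPM and the neurofilament gene Nefl at 61.9 ± 1.71 against 10.7 ± 0.45 TPM. Of 49 germline genes 47 were higher in Ring1b-KO and 2 lower (47 and 2 adjusted over the list alone), with a median of 2.14. Hox genes were higher in 35 of 37 cases with 2 not called (35 adjusted over the list alone), and 2-cell-like genes in 20 of 20 (20 adjusted over the list alone), genes under 1 TPM in WT that were tested only through knockouts where they are high. Of the other homeobox genes 59 of 69 were higher and 10 not called (60 higher and 2 lower adjusted over the list alone). With an estimated correlation the adjusted p was 5.03e-04 for germline genes, 3.84e-04 for Hox genes, 3.49e-04 for 2-cell-like genes and 7.91e-04 for the other homeobox genes. Trophoblast genes were higher in 13 of 21, lower in 2 and not called in 6 (14 and 3 adjusted over the list alone), with an adjusted p of 0.0138, which was 0.138 with an estimated correlation. In all 9105 genes were called, 6051 higher and 3054 lower, and 1880 changed at least 2-fold. The median log2 change of all genes was 0.12, and the share called higher was 66.5%, 61.4% under median ratio scaling and 48.1% with quantile normalization.

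The double knockout and Ring1b-KO differ by Ring1a in their labels, but Rnf2 was also lower in the double knockout, at 22.8 ± 2.94 against 49.4 ± 3.13 TPM (adjusted p = 1.99e-08). Its 2-cell-like genes were lower and its trophoblast genes higher. Zscan4f was at 0.39 ± 0.15 TPM in the double knockout and 19.8 ± 0.83 TPM in Ring1b-KO (log2 fold change -3.90 ± 0.11, adjusted p = 4.22e-13), and Zscan4c at 0.07 ± 0.02 and 11.8 ± 0.72 TPM. Nanog was at 36.3 ± 1.86 against 387 ± 10.6 TPM (-3.38 ± 0.05, adjusted p = 3.26e-16), H19 at 4.75 ± 0.89 against 68.4 ± 3 TPM, and Dazl at 11.7 ± 0.94 against 87.0 ± 2.02 TPM. Higher in the double knockout were Hand1 (154 ± 6.66 against 16.5 ± 0.57 TPM), Cdx2 (8.83 ± 0.15 against 1.02 ± 0.33 TPM), the annexin gene Anxa1 (117 ± 1.14 against 7.92 ± 0.51 TPM) and S100a6 (776 ± 6.76 against 65.1 ± 4.92 TPM). Each of the 20 2-cell-like genes was lower (20 adjusted over the list alone), with a median of -2.24. As none was at 1 TPM in WT, these genes were tested only through knockouts where they are high, Ring1b-KO among them, so that this count is largely set by the filter. Hox genes were higher in 34 of 37 with 3 not called (35 adjusted over the list alone), the other homeobox genes in 64 of 69 with 1 lower and 4 not called (65 and 1 adjusted over the list alone), and trophoblast genes in 16 of 21 with 5 not called (17 adjusted over the list alone). With an estimated correlation the adjusted p was 5.56e-05 for 2-cell-like genes, 0.00938 for Hox genes, 7.22e-04 for the other homeobox genes and 0.00415 for trophoblast genes. Germline genes were higher in 21 of 49, lower in 13 and not called in 15 (22 and 13 adjusted over the list alone), a list with a median of 0.09 and a test in the other direction that was not called (adjusted p = 0.614). In all 10692 genes were called, 7334 higher and 3358 lower, and 2285 changed at least 2-fold. The median log2 change of all genes was 0.17, and the share called higher was 68.6%, 55.4% under median ratio scaling and 52% with quantile normalization.

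The interaction asks whether the double knockout departs from the sum of the single knockouts. It was called for 8688 genes, 5915 above the sum and 2773 below it, and 2568 of them departed at least 2-fold. The targeted gene Rnf2 itself lay below the sum (log2 -1.49 ± 0.11, adjusted p = 6.75e-08). Nanog lay below the sum (log2 -3.70 ± 0.07, adjusted p = 1.82e-14), as did Zscan4f (-3.95 ± 0.15, adjusted p = 5.03e-11), H19 (-4.11 ± 0.14, adjusted p = 1.38e-11) and the oocyte homeobox gene Obox6 (-4.37 ± 0.25, adjusted p = 3.12e-09). Above it were the galectin gene Lgals1 (3.81 ± 0.06, adjusted p = 2.55e-15), the immediate early gene Egr1 (3.56 ± 0.09), Krt18 (2.72 ± 0.08), Hand1 (2.53 ± 0.08) and Cdx2 (2.39 ± 0.15). Hox genes lay above the sum in 28 of 37 cases with 9 not called (29 adjusted over the list alone), the other homeobox genes in 58 of 69 with 11 not called (60 and 1 adjusted over the list alone), and trophoblast genes in 15 of 21 with 2 below and 4 not called (15 and 2 adjusted over the list alone). The 2-cell-like genes lay below it in 19 of 20 with 1 not called (20 adjusted over the list alone), a count that the filter favours, since they were tested through knockouts such as Ring1b-KO. These 4 lists were called with both correlations, at an adjusted p with an estimated correlation of 0.014 for Hox and for trophoblast genes, 7.44e-04 for the other homeobox genes and 5.15e-05 for 2-cell-like genes. The median over all genes was 0.15, and the share above the sum was 68.1%, 54.5% under median ratio scaling and 53.6% with quantile normalization.

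Pcgf-6KO and Pcgf-4KO differ by Pcgf2 and Bmi1 in their labels, but not in these alone in their transcripts. Pcgf2 was at 16.8 ± 1.28 TPM in Pcgf-6KO and 55.3 ± 2.13 TPM in Pcgf-4KO, Bmi1 at 15.6 ± 1.09 and 11.4 ± 2.42 TPM (not called, adjusted p = 0.0645), and Pcgf6 at 10.6 ± 0.78 and 0.06 ± 0.05 TPM. Hox and 2-cell-like genes were higher and pluripotency genes lower. Hoxd13 was at 11.7 ± 0.73 TPM in Pcgf-6KO and 2.03 ± 0.18 TPM in Pcgf-4KO (log2 fold change 2.07 ± 0.12, adjusted p = 1.90e-09), Hoxa2 at 8.13 ± 0.6 and 0.15 ± 0.09 TPM, and Hoxb2 at 5.2 ± 0.65 TPM, against a value listed at 0. Dlx2 was at 10.2 ± 0.16 and 0.58 ± 0.04 TPM. The keratin gene Krt8 was at 2228 ± 35.4 against 455 ± 18.1 TPM, Hand1 at 525 ± 16.5 against 169 ± 5.15 TPM and Tfap2a at 9.32 ± 0.7 against 0.99 ± 0.12 TPM. Nanog was lower, at 24.5 ± 0.95 against 117 ± 2.1 TPM (-2.22 ± 0.05, adjusted p = 7.48e-14), as were Sox2 (46.8 ± 1.39 against 172 ± 4.22 TPM), Fgf4 (11.9 ± 1.16 against 68.7 ± 1.41 TPM), Tdgf1 (32.5 ± 1.39 against 156 ± 1.98 TPM) and the demethylase gene Tet1 (22.5 ± 8.87 against 111 ± 2.77 TPM). Meg3 was at 109 ± 8.24 against 2.99 ± 0.81 TPM, and Otx2 at 9.94 ± 0.66 against 0.29 ± 0.18 TPM. All 37 Hox genes were higher (37 adjusted over the list alone), with a median of 1.61, and all 20 2-cell-like genes (20 adjusted over the list alone), with a median of 1.57. Both counts are favoured by the filter, since these genes were under 1 TPM in WT and passed it through knockouts such as Pcgf-6KO. Of 69 other homeobox genes 44 were higher, 3 lower and 22 not called (45 and 4 adjusted over the list alone), and of 21 trophoblast genes 16 were higher, 2 lower and 3 not called (16 and 2 adjusted over the list alone). Core pluripotency genes were lower in 17 of 18 with 1 not called (17 adjusted over the list alone) and naive pluripotency genes in 20 of 22 with 2 not called (20 adjusted over the list alone). With an estimated correlation the adjusted p was 1.25e-04 for Hox genes, 1.86e-04 for 2-cell-like genes, 0.00663 for the other homeobox and the trophoblast genes, and 0.0128 for both pluripotency lists. In all 9422 genes were called, 5147 higher and 4275 lower, and 1691 changed at least 2-fold, 1368 higher and 323 lower. The share called higher was 54.6%, 59.6% under median ratio scaling and 41.3% with quantile normalization.

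Pcgf-6KO compared with the double knockout sets the labelled loss of all Pcgf proteins against that of both catalytic subunits. H19 was at 486 ± 23.3 TPM in Pcgf-6KO and 4.75 ± 0.89 TPM in the double knockout (log2 fold change 6.42 ± 0.10, adjusted p = 1.13e-15), Mest at 61.8 ± 3.42 and 2.07 ± 0.19 TPM, and Zscan4f at 13.96 ± 1.83 and 0.39 ± 0.15 TPM. Krt8 was at 2228 ± 35.4 and 432 ± 12.9 TPM, and the placental gene Plac1 at 13.0 ± 0.49 and 1.14 ± 0.12 TPM. Lower in Pcgf-6KO were Efhc2 (0.89 ± 0.08 against 23.0 ± 1 TPM), Lefty2 (5.61 ± 1.33 against 81.5 ± 1.52 TPM), Sox2 (46.8 ± 1.39 against 136 ± 1.46 TPM), Tdgf1 (32.5 ± 1.39 against 154 ± 3.09 TPM) and the neural genes Olig1 (3.77 ± 0.68 against 19.7 ± 0.56 TPM) and Neurog1 (1.55 ± 0.13 against 8 ± 0.42 TPM). Gata4, Gata6 and Cdx2 were not called, at 13.8 ± 0.81 against 15.2 ± 0.71, 8.95 ± 1.25 against 9.86 ± 0.82 and 9.33 ± 0.87 against 8.83 ± 0.15 TPM. All 20 2-cell-like genes, which passed the filter through knockouts such as Pcgf-6KO, were higher in Pcgf-6KO (20 adjusted over the list alone), with a median of 1.99, and 15 of 21 trophoblast genes, with 1 lower and 5 not called (15 and 1 adjusted over the list alone), with a median of 0.71. Their adjusted p with an estimated correlation was 1.85e-04 and 0.0094. Of 37 Hox genes 11 were higher, 9 lower and 17 not called (11 and 9 adjusted over the list alone), with an adjusted p of 0.402. Core pluripotency genes were lower in 17 of 18 with 1 not called (17 adjusted over the list alone) and the other homeobox genes in 41 of 69, with 8 higher and 20 not called (41 and 8 adjusted over the list alone), both called with the preset correlation and both at an adjusted p of 0.0742 with an estimated correlation. In all 10341 genes were called, 5055 higher and 5286 lower, and 2037 changed at least 2-fold, 1366 higher and 671 lower. The share called higher was 48.9%, 50.8% under median ratio scaling (5340 higher and 5179 lower) and 43.7% with quantile normalization (4693 and 6041), so the larger side depends on the scaling.

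The knockouts shared many called genes. The double knockout and Pcgf-6KO had 9225 genes called in the same direction against WT, 6973 higher and 2252 lower, and 560 in opposite directions, where 5116 shared genes would come from independent sets of these sizes. Pcgf-4KO and Pcgf-6KO shared 9560 genes (5062 for independent sets) and Ring1b-KO and the double knockout 6077 (3495 for independent sets), with 479 and 953 in opposite directions. Fold changes across genes correlated at r = 0.734 between the double knockout and Pcgf-6KO, 0.764 between Pcgf-4KO and Pcgf-6KO and 0.546 between Ring1b-KO and the double knockout, against 0.497, 0.499 and 0.499 in 100 simulations with no effect and shared WT libraries, and genes are not independent replicates. The covariance of fold changes exceeded the simulated one by 0.598, 0.653 and 0.269. The same 3 WT libraries served all comparisons. In the simulations these shared libraries gave a covariance of 0.032, 0.033 and 0.033 against 0.631, 0.685 and 0.301 observed. Noise between the WT libraries therefore accounts for little of the covariance, although the simulated noise was independent for each gene. The simulations also gave at most 0 shared calls. As no gene was changed in them, hardly any call was possible, so this count does not bear on the overlaps. How much this noise adds to the numbers of shared calls was not tested. A trait common to the 3 WT libraries was not simulated, so part of each overlap may still be theirs. Of the 2584 genes that rose at least 2-fold in Pcgf-4KO 2104 (81.4%) also did in Pcgf-6KO, among them Hand1 and H19. Of the 3036 in the double knockout 2159 (71.1%) also rose at least 2-fold in Pcgf-6KO and 1966 (64.8%) in Pcgf-4KO. Of the 1472 in Ring1b-KO 820 (55.7%) did in the double knockout.

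Several chromosomes also differed between groups. Relative to WT and to all genes, the 294 tested genes of chromosome 16 at a mean of 10 TPM or more had a median log2 difference of 0.22 ± 0.023 in Ring1a-KO, -0.23 ± 0.009 in Ring1b-KO, 0.26 ± 0.012 in the double knockout, 0.27 ± 0.014 in Pcgf-4KO and 0.29 ± 0.023 in Pcgf-6KO (n = 3 libraries each). The SD among WT libraries was 0.006. Chromosome 6 lay at -0.33 ± 0.028 in Pcgf-6KO (366 genes) and chromosome 11 at -0.13 ± 0.004 in Ring1b-KO (779 genes). Further medians beyond 0.1 were 0.14 ± 0.01 for chromosome 19, 0.11 ± 0.016 for chromosome 12 and -0.10 ± 0.049 for the X chromosome in Pcgf-6KO. In the double knockout they were -0.12 ± 0.023 for chromosome 13, -0.11 ± 0.009 for chromosome 6 and 0.10 ± 0.01 for chromosome 11. Pcgf1 and Mest lie on chromosome 6 and Pcgf2 and Hand1 on chromosome 11. Several transcripts of the Y chromosome were near 0 in 3 of the knockouts and lowered in part in Ring1b-KO. Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629) was at 17.96 ± 1.13 TPM in WT, 0.01 ± 0.01 in Ring1a-KO, 0.02 ± 0.02 in the double knockout and 0.02 ± 0.03 in Pcgf-4KO, and at 3.68 in Ring1b-KO and 22.1 ± 3.32 in Pcgf-6KO. Eif2s3y (ENSMUSG00000069049, chromosome Y, 1010543 to 1028847) was at 41.9 ± 1.59 TPM in WT, 0.07 ± 0.08 in Ring1a-KO, 0.09 ± 0.12 in the double knockout and 1.98 ± 0.44 in Ring1b-KO. It was listed at 0 in Pcgf-4KO, and was at 13.8 ± 1.36 in Pcgf-6KO, below WT where Ddx3y was not. Mid1, annotated to the X chromosome, followed the same groups, at 1.49 ± 0.08 TPM in Ring1a-KO, 1.5 ± 0.22 in the double knockout and 1.32 ± 0.12 in Pcgf-4KO, against 62.5 ± 1.02 in WT, 54.8 ± 4.46 in Ring1b-KO and 56.1 ± 10.4 in Pcgf-6KO. So did the Y-linked Mid1-ps1, picked after its values were seen, at 1.45, 1.73 and 2.24 TPM against 8.4, 9.46 and 9.41 TPM. The falls of Mid1 thus cannot be told apart from whatever lowered the Y-linked transcripts.

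**Figure D4:**
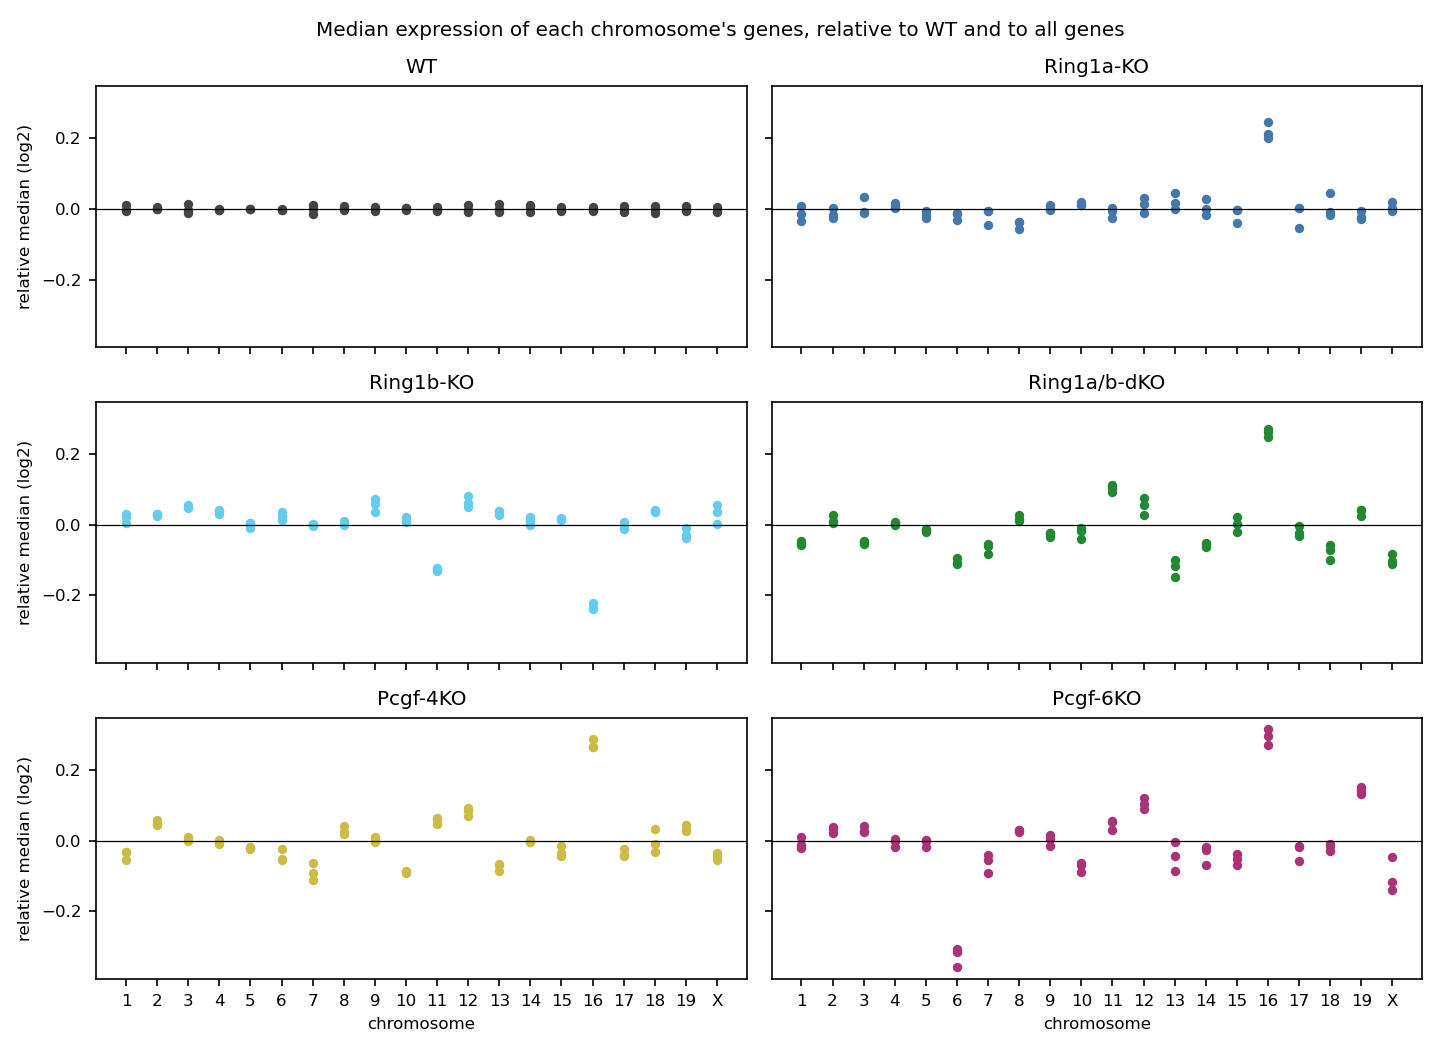
Median log2 difference of the genes of each chromosome (1 to 19 and X, horizontal axis) from WT and from all genes (vertical axis), with a dot per library and a panel per group. Chromosome 16 lies at -0.23 in Ring1b-KO and between 0.22 and 0.29 in the other knockouts.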

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

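The libraries labelled as the double knockout differed from the sum of those labelled as single knockouts by a test of the difference itself, which is what brought this result here. Loss is by label, since Ring1 was not called in Ring1a-KO or the double knockout and Rnf2 was lowered but still present. Rnf2 also lay below the sum in the double knockout (interaction log2 -1.49 ± 0.11, limma adjusted p = 6.75e-08). Whether interactions of other genes follow this deeper fall of Rnf2 was not tested. The interaction was called for 8688 genes, against 5086 in the highest other of the drawn regroupings of the 12 libraries, so the real grouping was 1 of 100 in rank. Regroupings that mix libraries of different groups add the group differences to the spread. This rank therefore cannot tell an interaction from any other difference between the groups. The median log2 interaction was 0.689 for Hox genes, 1.119 for the developmental homeobox genes outside the Hox clusters and 1.194 for trophoblast genes, so these lay above the sum. For 2-cell-like genes it was -2.227, since their rise in Ring1b-KO (20 of 20 genes) was largely missing in the double knockout (2 of 20). These 20 genes were under 1 TPM in WT and were tested through the knockouts where they are high, which favours this direction. The labels do not separate clone or culture from genotype.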

How the results depend on the processing

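Of 17484 values of single genes under alternatives (1050 main values), 16738 kept their call or lack of one, 716 lost the call, 26 gained it and 4 changed sign. Of 2818 list values (175 main values) 2667, 125, 20 and 6 did so, where the last count is of changes in the direction of the list test. Changes of sign or direction were counted only for values called in the main setting or the alternative. Values called in neither were counted as kept, whatever their sign. With a minimum change of 2-fold, which asks for more by construction, the counts against WT were 302 for Ring1a-KO, 1894 for Ring1b-KO, 3544 for the double knockout, 3293 for Pcgf-4KO and 5327 for Pcgf-6KO. They were 1880 for Ring1b-KO against Ring1a-KO, 2285 for the double knockout against Ring1b-KO, 1691 and 2037 for Pcgf-6KO against Pcgf-4KO and the double knockout, and 2568 for the interaction. Shared calls were 2560 for the double knockout and Pcgf-6KO, 2620 for Pcgf-4KO and Pcgf-6KO and 1038 for Ring1b-KO and the double knockout. With the estimated inter-gene correlation the called lists went from 12 to 1 in Ring1a-KO, 15 to 6 in Ring1b-KO, 16 to 6 in the double knockout, 16 to 3 in Pcgf-4KO, 18 to 6 in Pcgf-6KO, 18 to 6 for Pcgf-6KO against Pcgf-4KO and 16 to 2 for Pcgf-6KO against the double knockout. Without genes on chromosomes 6, 11, 16 and Y 4 pairs of a targeted gene and a knockout of it were called lower in place of 7, since the 2 pairs of Pcgf1 and the 1 of Pcgf2 were removed. Without the Ring1a-KO libraries of replicates 2 and 3 2169 genes were called in Ring1a-KO, from 1 library assumed to vary like the other groups. The counted changes of sign were for Rpl23 in the double knockout (-0.016, median ratio scaling), Nanog in Pcgf-4KO (-0.099, and -0.009 with quantile normalization) and Zfp42 in Pcgf-6KO (-0.038, quantile normalization). For lists the direction of the test, which is relative to all other genes, was followed in place of the sign of the median. With quantile normalization it turned for the ribosomal protein list, at a median of 0.059 in Ring1b-KO, -0.005 in the double knockout and -0.011 in Pcgf-6KO. It also turned for the mitochondrially encoded list in Pcgf-4KO, at a median of 0. The histone list in Ring1a-KO went to -0.087 without the libraries of replicates 2 and 3, and ranged from 0 to 0.579 when single libraries were left out. For these changes of sign or direction the cause was not tested. Leaving out 1 library gave 3242 to 3620 called genes in Ring1a-KO and 8 to 13 called lists, 8 without Ring1a-KO replicate 2. In the other comparisons with WT it gave 8317 to 8474, 10770 to 10854, 10841 to 10980 and 12669 to 13167 genes. A replicate block, which pairs equal numbers, gave 3994 to 13204 genes in the comparisons with WT and changed no count by more than 1.5 times. The numbers paired are those of the sample titles, while the deposited columns number the WT libraries 4 to 6 and the knockout libraries 1 to 3. Libraries of equal number did not pair (mean r 0.001 over 45 pairs, 8 of 18 libraries closest to their own number). Depth is unknown, and a value of 0 may hide transcripts of low level.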

Other observations

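Glycolysis and hypoxia genes, which follow oxygen and sugar supply, fell in 17 of 22 cases in the double knockout, with 4 higher and 1 not called (17 and 4 adjusted over the list alone), and in 16 in Pcgf-6KO, with 5 higher and 1 not called (16 and 5 adjusted over the list alone). Their medians were -0.62 and -1.02, with an adjusted p of 1.94e-09 and 2.27e-07 that became 0.0531 and 0.0825 with an estimated correlation. The kinase gene Pdk1, a switch away from mitochondrial oxidation, fell from 69.98 ± 0.61 to 13.5 ± 0.68 and 6.07 ± 1.01 TPM, while the vessel growth factor gene Vegfa rose from 9.63 ± 0.75 to 40.19 ± 3.5 and 28.2 ± 1.81 TPM. Cholesterol synthesis genes fell in 17 of 24 cases in Pcgf-6KO, with 2 higher and 5 not called (17 and 2 adjusted over the list alone), with Insig1 at 23.5 ± 2.31 against 72.2 ± 1.56 TPM, and their adjusted p was 2.30e-07, or 0.0825 with an estimated correlation. Integrated stress response genes rose in 10 of 20 cases and fell in 10 (10 and 10 adjusted over the list alone), with Ddit3 at 64.8 ± 6.66 against 5.71 ± 0.96 TPM and the amino acid enzyme gene Mthfd2 at 20.2 ± 0.97 against 81.8 ± 0.95 TPM, and the list was not called with a median of 0.03 and a mean of 0.19 but a test in the lower direction (list adjusted p = 0.143). Ligand genes rose in 25 of 35 and fell in 9 with 1 not called (25 and 9 adjusted over the list alone), with Bmp8b at 42.0 ± 7.4 against 2.94 ± 0.38 TPM, and the list was not called (list adjusted p = 0.299). Imprinted genes rose in 20 of 33 and fell in 9 with 4 not called (20 and 9 adjusted over the list alone), among them the neuronal gene Nnat, which fell from 33.9 ± 2.03 to 8.39 ± 0.78 TPM, and this list was not called either (list adjusted p = 0.333).

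Fibroblast markers rose in 11 of 17 cases in Pcgf-6KO and fell in 4 with 2 not called (11 and 4 adjusted over the list alone). The actin-binding gene Tagln rose from 16.4 ± 2.65 to 108 ± 7.44 TPM and fibronectin (Fn1) fell from 276 ± 3.44 to 78.6 ± 18.8 TPM, and the list was not called (list adjusted p = 0.658). Neuroectoderm genes rose in 12 of 27 and fell in 12 with 3 not called (12 and 12 adjusted over the list alone), with Zic1 at 8.5 ± 0.83 against 0.03 ± 0.04 TPM and Stmn2 at 17.1 ± 0.95 against 161 ± 4.39 TPM, a list that was not called (list adjusted p = 0.0745). Of 28 PRC1 subunits not targeted 14 rose, 7 fell and 7 were not called (14 and 7 adjusted over the list alone), with a list adjusted p of 0.854, and of 13 PRC2 subunits 4 rose, 6 fell and 3 were not called (4 and 6 adjusted over the list alone), with a list adjusted p of 0.0854. Cbx8 reached 21.9 ± 1.3 TPM, Aebp2 rose from 30.1 ± 1.62 to 61.9 ± 9.84 TPM and Jarid2 fell from 191 ± 4.31 to 91.1 ± 13 TPM. Of 13 mitochondrially encoded genes 10 fell and 3 were not called (10 adjusted over the list alone), with a median of -0.52 and an adjusted p of 2.88e-05 that was 0.115 with an estimated correlation, a call that ended with quantile normalization at -0.51.

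The tests of the next 3 patterns were chosen after the results had been seen. Chromosome 16 was shifted in all 5 knockouts. A few strongly changed genes on the chromosome do not account for this, since the share of its genes on the side of its median was at least 64.6%, where the highest share was 57 to 58.6% on 16 other autosomes, but chromosomes 6 and 11, left out of these 16 because they were seen to shift, had 65.3% in Pcgf-6KO and 63.8% in Ring1b-KO. Rises of genes low in WT do not account for it either, since its genes at 20 TPM or more in WT had a relative median at least 0.227 from 0. A different copy number of the chromosome in these cultures may be the source, with at least 9 of 10 position bins on the same side, but other autosomes also reached 9, so this test is weak. No DNA was measured, and a biological effect of PRC1 loss on this chromosome was not separated from a difference between lines.

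Y-linked transcripts were near 0 in Ring1a-KO, the double knockout and Pcgf-4KO, and lowered in part in Ring1b-KO, with Eif2s3y at 1.98 against 41.85 TPM, Uty at 1.21 against 6.81 TPM, Ddx3y at 3.68 against 17.96 TPM and Kdm5d at 0.98 against 2.88 TPM. Of the 13 genes annotated to the Y chromosome at 1 TPM or more in WT, 6 lay under 10% of WT in all 3, among them the gene model Gm47283. Absence of the Y chromosome as the only source of their levels predicted all 13, so the count went against it. The rest were the pseudogenes Mid1-ps1 and Gapdh-ps15 and the gene models Gm21860, Gm21748, Gm28595, Gm21742 and Gm37158. Whether their TPM includes reads of similar genes on other chromosomes was not tested, so this count cannot decide the question. Kdm5d, Uty, Ddx3y, Eif2s3y and Uba1y were then picked, after that count and after being seen low, and 5 of 5 lay under 10%, so absence of the Y chromosome from most cells of these cultures may explain these 5 but stays open. Cells with 2 active X chromosomes in place of the labelled line do not account for it, since the relative median of X-linked genes was at most -0.001 in the 3 knockouts. Cells with 2 X chromosomes of which 1 is silent would not raise this median, so the test cannot exclude them. No biological explanation was tested.

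Rises outnumbered falls in Pcgf-6KO, at 79.3% of the genes changed at least 2-fold. One scaling factor per library, from the fixed total of TPM, does not account for all of it, since 71.8% were still higher under median ratio scaling. The share was lower than the 79.3% before this scaling, so part of the excess depends on it. This test was added after the quantile result was seen. A level-dependent difference in the spread of values could be the source, because quantile normalization, which forces the spread to be equal, gave 52%, and this leaves it undecided whether the excess is technical or a loss of repression by PRC1. That genes near 0 in WT can only rise does not account for all of it, since 71.4% were higher among genes at 5 to 20 TPM in WT (42.9% with quantile normalization), though at 20 TPM or more 45.8% were.

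Libraries were also regrouped within each comparison. The real grouping was 1 of 10 splits in rank in each comparison with 6 libraries, and 10 splits are too few for a share under 0.05. Every other split also puts libraries of both groups on each side. The real difference then adds to the spread, so few gene calls are left by construction, and these counts do not show what chance would give. Called genes in Ring1a-KO, Ring1b-KO, the double knockout, Pcgf-4KO and Pcgf-6KO against WT were 4123, 9247, 11489, 11602 and 13236, where the highest other split gave 1, 2, 0, 1 and 1 (limma). For Ring1b-KO against Ring1a-KO, the double knockout against Ring1b-KO, and Pcgf-6KO against Pcgf-4KO and the double knockout they were 9105, 10692, 9422 and 10341, where it gave 14, 2, 1 and 2. Called lists came closer. They were 12, 15, 16, 16 and 18 against WT, where the highest other split gave 9, 12, 14, 15 and 17, and 18 and 16 for Pcgf-6KO against Pcgf-4KO and the double knockout, where it gave 15 and 14. Shared calls of the double knockout and Pcgf-6KO (9225) were 1 of 100 in rank, with 8857 in the highest other regrouping, which kept a whole group as control. Those of Pcgf-4KO and Pcgf-6KO (9560) were 1 of 100, with 1 in the highest other, but 0 of the regroupings drawn for this pair kept a whole group as control. Those of Ring1b-KO and the double knockout (6077) were 2 of 100, and a regrouping with another whole group as control gave 7451. With a mixed control the highest was 2, 1 and 1 for the 3 pairs in this order, so these regroupings do not set the pairs apart.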
